A study of Mus musculus with 2 samples.

How the data were processed

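Gene expression was measured in 2 individual cells from dissociated CD1 mouse retina, 1 at embryonic day 12.5 and 1 at postnatal day 0, each on its own array. Per the labels' protocols, retinas were dissociated with papain, cells were picked by capillary, and oligo dT primed cDNA was tailed and amplified by 35 cycles of PCR. A total of 10 micrograms of each cDNA were fragmented and labelled with biotin, and the array was an Affymetrix mouse expression array. Priming at the poly(A) tail favours the 3' ends of transcripts, and reverse transcription from a single cell can lose a transcript altogether, so a gene below background was not detected and cannot be called absent. The ages and the assignment of both cells to the ciliary body come from the labels. The assignment was made by the submitters from gene expression after the arrays were read.

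The deposited values are signal intensities on a linear scale, 1 per probe set and cell, computed by the authors with MAS5, per the series' design text and the submitters' processing notes. MAS5 subtracts mismatch signal from perfect-match signal and scales each array on its own. The values themselves show the scaling: the mean over probe sets, leaving out 2% at each end, was 500.0 in both arrays. Signals ran from 0.225 to 147582 in the E12.5 cell and from 0.29 to 289883 in the P0 cell. The table holds no detection calls and no replicate arrays, so depth in reads does not apply and no interval was computed. Scanner files were not used here. The software version and settings are not given in the sources used here.

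Of 45101 probe sets, 34958 had 1 gene symbol in GEO's platform annotation, 932 had several and 9211 were not listed there. Symbols of 34754 probe sets were taken by gene identifier from a RefSeq annotation of assembly GRCm38.p6, and the other 204 kept the platform's name. No genome build is named for the signals, so no coordinates are given. Probe sets with several or no symbols name no gene here. Each of the 18194 genes was represented by the probe set with the highest mean log2 signal over the 2 cells.

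The background limit of an array was the 99th percentile of the signals of probe sets for olfactory, vomeronasal and taste receptors, keratin-associated proteins, intestinal defensins, protamines, caseins, major urinary proteins, prolactin relatives, zona pellucida proteins and other families with no known role in the eye. The naming pattern for caseins, fixed before the data were examined, also took in 32 probe sets of casein kinases, which most cells express. They were removed after the values had been seen, leaving 205 of 237 probe sets, which departs from the rule as first written. With them the limits were 3068 and 4509, and 26 and 7 genes were called higher in the P0 and the E12.5 cell, in place of 1721 and 1365. A gene was called higher in 1 cell when its signal there exceeded that array's limit and the ratio was 4 or more, each signal having first been raised to its array's limit. Where the dimmer cell was below its limit, the fold is a lower bound, written "at least". Because the 2 limits differ, a gene just above the lower limit in the E12.5 cell can have a ratio on the P0 side; no fold is given for it.

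The 34 gene lists, covering cell types, the cell cycle, signalling pathways and general cell functions, and the rules for limits, calls and named genes were fixed before the data were examined. Counts refer to members with a probe set of 1 gene symbol. A list with at least 5 members above the limit in at least 1 cell has its median log2 ratio compared with 10000 random lists of the same size, matched on mean signal in 20 bins. Genes below a limit enter that median at their bound. Genes named were the 12 with the largest ratio in each direction, leaving out clone and predicted names, and members of the fixed lists. A few genes of lists written later appear under the other observations. With 1 cell per group no test between groups was possible. The spread between probe sets of the same gene stands in as a measure of array error and contains no variation between cells. It was taken from probe sets above the limit in both cells, so it does not cover calls with the dimmer cell below its limit. Probe sets of a gene are read from the same amplified cDNA, so loss of a whole transcript is not in it either.

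The scoring was tested on simulated data for the comparison of the P0 with the E12.5 cell: 200 of 18194 genes were changed in arrays drawn from the E12.5 signals with log2 noise of SD 0.3. The changed genes were picked only among those with an E12.5 signal over 16 times the limit, which makes recovery easy. Recovery of weaker genes was not simulated. All genes changed 8-fold or 16-fold were recovered, 67.9% of those changed 4.5-fold were, and 0 unchanged genes were called. With noise of SD 0.6 per array, which gives the ratio the SD of 0.85 seen between probe sets of a gene, 57.1%, 89.6% and 100% of those changed 4.5-fold, 8-fold and 16-fold were recovered and 90 of 17994 unchanged genes were called. Most of the unchanged genes lay below the limit, where a call is unlikely, so the share called among brighter genes was higher. Neither simulation contains loss of transcripts or variation between cells. Of 200 random lists of 15 genes, 6 lay outside the 2.5th to 97.5th percentiles.

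Alternatives tried were a limit at the 95th percentile, a limit from unspiked bacterial control probe sets, quantile normalisation, the mean over probe sets, leaving out probe sets that can hybridise to related transcripts, centring on shared genes, a pseudocount of 100 in place of the limit, thresholds of 2-fold and 8-fold, no filter, and random lists without matching. A further 2 were added after the data were seen: the casein kinases kept, and arrays scaled to the median of 18 hybridisation spike-in probe sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.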

Results

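The 2 expression profiles each came from 1 cell of a dissociated retina of CD1 mice, an albino outbred strain. One cell was taken at embryonic day 12.5 (E12.5), when the optic cup is growing and its first neurons are born, and the other on the day of birth (P0). The submitters had classified cells by their expression after the arrays were read: 21 cells as young neurons or photoreceptors and 42 as cycling progenitors, none of which is analysed here. The 2 cells described here scored for no retinal cell type and were assigned to the developing ciliary body and iris region, the rim of the optic cup. The questions addressed are which genes the 2 peripheral cells share and how the E12.5 and P0 cells differ. With 1 cell per age there is no replicate check: each difference below is between these 2 cells, and no p-value or standard error is given. The number of arrays limits the precision.

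Each array held 45101 probe sets. The median signal was 43.2 in the E12.5 cell and 42.2 in the P0 cell, and the signal at the 90th percentile was 2110 and 2235. The background limit, taken from 205 probe sets of genes with no known role in the eye, was a signal of 237 in the E12.5 cell and 335 in the P0 cell. Of 18194 named genes, 5598 (30.8%) exceeded the limit in the E12.5 cell and 5194 (28.5%) in the P0 cell. A total of 3440 genes exceeded it in both, where independent lists of these lengths would share 1598. They were 61.5% of the E12.5 cell's genes and 66.2% of the P0 cell's. Across these shared genes, which are not independent replicates, the log2 signals of the cells correlated with a Pearson coefficient of 0.52 and a Spearman coefficient of 0.50, and the log2 ratio of P0 over E12.5 had a median of 0.02 and an SD of 1.49. Different probe sets of the same gene, available for 987 shared genes, differed in their log2 ratio with an SD of 0.85.

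**Figure D1:**
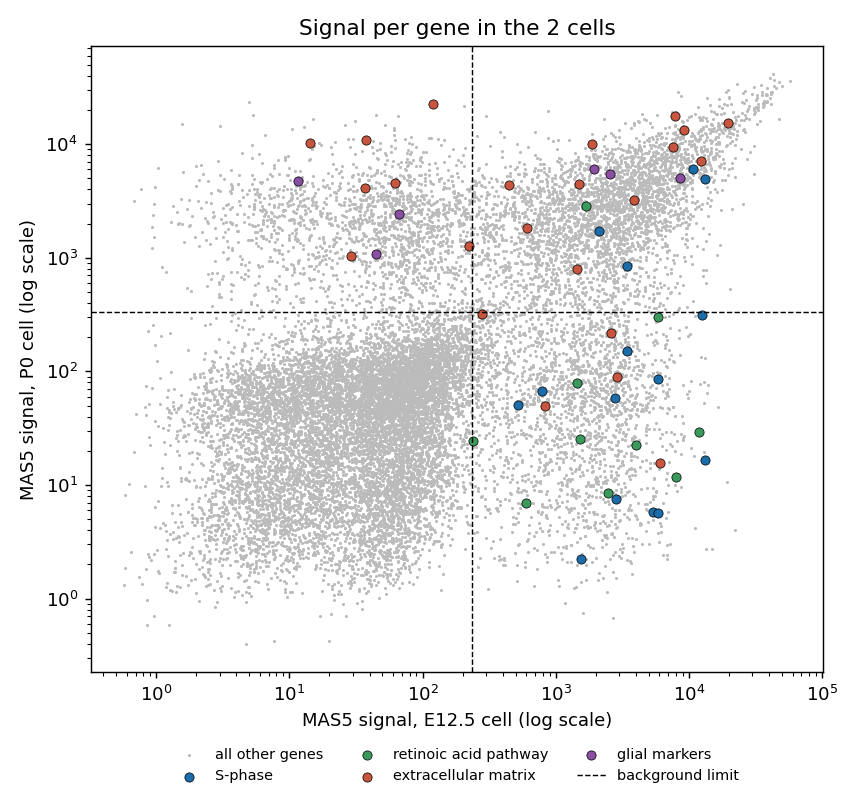
MAS5 signal of each of 18194 genes in the E12.5 cell (x axis, log scale) and the P0 cell (y axis, log scale), 1 point per gene; coloured points are list members above the limit in at least 1 cell, and dashed lines mark the background limits of 237 and 335. Signals fall into a low and a high cloud on each axis, and the upper right quadrant holds the 3440 genes above the limit in both cells.

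Both cells expressed part of a ciliary margin marker list. Of its 20 genes, 9 were above background in the E12.5 cell, 8 in the P0 cell and 6 in both. These counts and those of the lists below stand against 30.8% and 28.5% of all named genes above background in the 2 cells. The shared members were the zinc finger transcription factors Zic1 (signal 19476 in the E12.5 cell and 9865 in the P0 cell) and Zic2 (4640 and 2787), cyclin D2 (Ccnd2, 14149 and 13623), the retinol dehydrogenase Rdh10 (1688 and 2831), the hedgehog co-receptor Cdon (12766 and 1193) and the secreted protein Wfdc1 (10696 and 414). Cdon was 10.7-fold and Wfdc1 25.8-fold higher in the E12.5 cell. The transcription factor Otx1, which is needed for the ciliary body, was at least 4.70-fold higher in the E12.5 cell, the gap junction protein gene Gja1 at least 7.52-fold and the zinc finger gene Mecom at least 17.0-fold, each lying below the limit in the P0 cell. Sox9, a transcription factor of progenitors and Müller glia, was at least 38.5-fold higher in the P0 cell, and the ligand gene Bmp7 at least 8.05-fold. Msx1, Msx2, Bmp4, Mitf, Wnt2b, Axin2, Lef1, Boc and Wls were above the limit in neither cell. Because the cells were assigned to this region by their expression, the list is not independent evidence of where they came from. A second probe set of Zic1 gave a ratio of the opposite sign, and only 2 of 5 further probe sets of Ccnd2 had the sign of the one reported. The second probe set of Sox9 had the same sign but did not reach 4-fold.

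Genes of the differentiating ciliary body and iris were above background in both cells as well, 8 of 16 in each and 6 in both. Type IX collagen (Col9a1) had a signal of 19719 in the E12.5 cell and 15215 in the P0 cell, and the fibrillin gene Fbn2 had 9161 and 13265, with a second probe set of Fbn2 going the other way. In all, 4 members were at least 4-fold higher in the P0 cell. They were Cp, which encodes the copper-binding plasma protein ceruloplasmin (at least 31.9-fold), Col18a1 (5.43-fold), Optc, which encodes the vitreous proteoglycan opticin (at least 5.28-fold), and the microfibril gene Mfap2 (4.22-fold). A second probe set of Mfap2 had the same sign but did not reach 4-fold. Foxp2, a transcription factor gene, and Slc12a2, a sodium-potassium-chloride cotransporter gene, were at least 22.6-fold and at least 8.16-fold higher in the E12.5 cell. The median log2 ratio of the 10 members measured in at least 1 cell was 0.95, at percentile 98.7 of 10000 random lists matched on signal and 84.9 of unmatched lists. The median was 0.16 when the arrays were scaled to the hybridisation spike-ins. Of 15 pigment cell genes, Trpm1 and Rab38 were above background in the E12.5 cell only, at least 18.8-fold and at least 6.85-fold higher there. Rlbp1, which encodes the retinaldehyde-binding protein of pigment epithelium and Müller glia, was above background in the P0 cell only. Tyr, the tyrosinase gene, was above background in neither. With the limit at the 95th percentile, 4 pigment cell genes were above it in the E12.5 cell and 3 in the P0 cell.

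**Figure D2:**
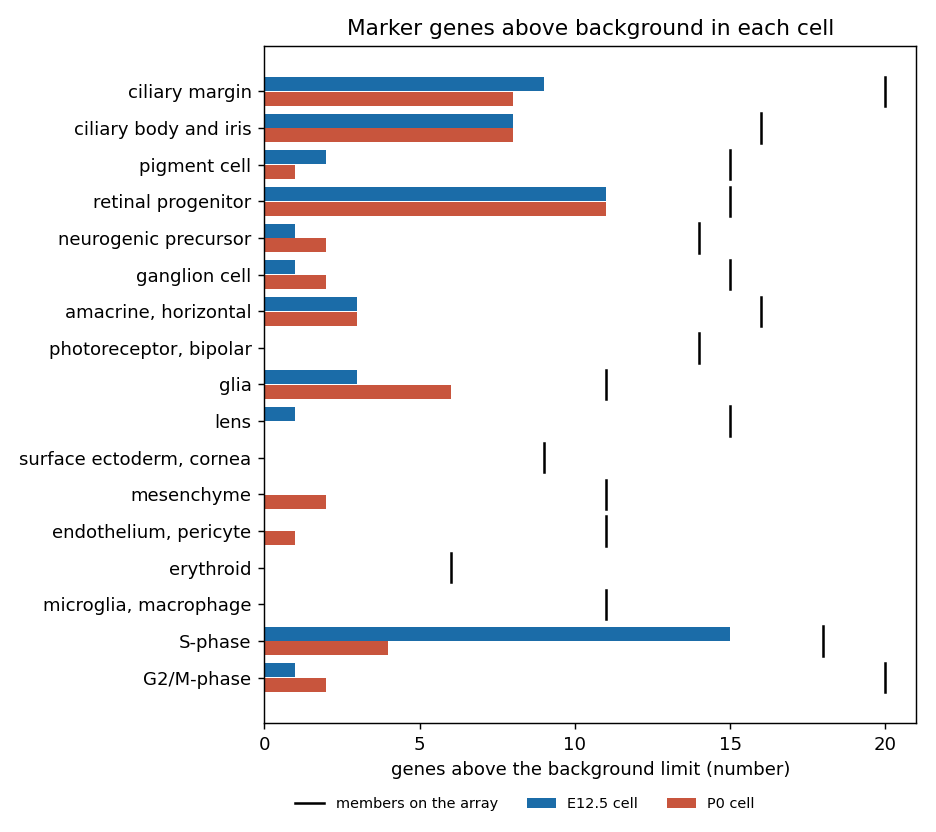
Number of marker genes above the background limit in the E12.5 cell (blue bars) and the P0 cell (red bars) for 17 lists; black ticks mark how many members had a usable probe set. Retinal progenitor markers reached 11 of 15 in each cell, S-phase genes 15 of 18 in the E12.5 cell against 4 in the P0 cell, and photoreceptor, erythroid, microglial and surface ectoderm markers 0 in both.

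Retinal progenitor genes were broadly expressed in both cells, with 11 of 15 above background in each and 9 in both. Of the 15, 5 were at least 4-fold higher in the E12.5 cell and 2 in the P0 cell. The eye field transcription factor genes Six3 (6099 in the E12.5 cell and 3322 in the P0 cell), Six6 (12089 and 5451) and Rax (949 and 494) and the stem cell factor gene Sox2 (10369 and 11739) differed by less than 4-fold. The secreted Wnt modulator gene Sfrp2 was 38.4-fold higher in the E12.5 cell, Pax6 15.4-fold and the Notch effector gene Hes1 8.63-fold. Cyclin D1 (Ccnd1) was at least 33.4-fold and the growth factor gene Fgf15 at least 26.9-fold higher there. The LIM homeobox gene Lhx2 was 7.28-fold and the nuclear receptor gene Nr2e1 at least 14.2-fold higher in the P0 cell. The list's median log2 ratio was -0.94, at percentile 3.42.

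Most members of the fixed lists for classes of retinal neurons were below background. None of 14 photoreceptor and bipolar genes was above the limit in either cell. Of 15 ganglion cell genes, 1 was above it in the E12.5 cell (Gap43, signal 1457) and 2 in the P0 cell (Ebf3, 1041, and Klf7, 565). Of 14 neurogenic precursor genes, Hes6 was above background in both cells (2990 and 4038), and Dlx2 in the P0 cell only, where it was at least 13.0-fold higher. Atoh7 and Neurog2 were above background in neither. Of 16 amacrine and horizontal cell genes, Gad2, which encodes a GABA-synthesising enzyme, was above background in both cells (4515 and 6459) while Gad1 was in neither, the GABA transporter gene Slc32a1 was above it in the E12.5 cell (438), and the glycine transporter gene Slc6a9 (480 and 2949) was 6.14-fold higher in the P0 cell. Calb1, encoding a calcium-binding protein, was at least 10.7-fold higher in the P0 cell. No neuronal class having been found for these cells was a condition of their choice, so these counts are not independent of it. With the limit at the 95th percentile, photoreceptor, ganglion cell and neurogenic genes above it numbered 1, 2 and 2 in the E12.5 cell and 3, 5 and 6 in the P0 cell, where 5 amacrine and horizontal cell genes were above it.

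Few markers of cell types from outside the retina were above the limit, and their number depended on it. No erythroid gene (of 6), microglial gene (of 11) or surface ectoderm and corneal gene (of 9) was above the limit in either cell. The crystallin gene Cryba2 was the only 1 of 15 lens genes, with a signal of 342 in the E12.5 cell. The pericyte gene Rgs5 was the only 1 of 11 vascular genes, with 833 in the P0 cell. Of 11 mesenchymal genes, the P0 cell had 2 above the limit, the collagen gene Col1a2 (2653) and the growth factor receptor gene Pdgfra (3088), and the E12.5 cell had 0. With the limit at the 95th percentile or from bacterial controls, the P0 cell had 5 lens, 4 vascular, 4 mesenchymal, 2 microglial and 2 surface ectoderm genes above it, and the E12.5 cell 2 lens, 2 vascular, 1 microglial and 2 surface ectoderm genes. In the E12.5 cell, 2 mesenchymal genes were above the limit at the 95th percentile and 1 was above that from bacterial controls. Erythroid genes stayed at 0 in both cells.

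In the comparison of the cells gene by gene, 1721 genes were at least 4-fold higher in the P0 cell and 1365 at least 4-fold higher in the E12.5 cell. For 1344 and 1123 of them, respectively, the dimmer cell was below its limit, so that the fold is a lower bound. Of all called genes 55.8% were higher in the P0 cell, a share that became 36.0% when the arrays were scaled to the spike-ins, which shifted the median log2 ratio of shared genes to -0.77. The share was 49.9% with the limit at the 95th percentile, 50.0% with bacterial controls, 50.2% with the pseudocount and 48.8% without a filter. The lower limit of the E12.5 cell lets a P0 call be made at a lower signal, so the excess of P0 calls depends on the limits. Among the 894 called genes with a second probe set above the limit in the brighter cell, all such probe sets had the same sign for 844, and at least 1 of them was itself 4-fold higher in that cell for 580.

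The 12 named genes with the largest excess in the P0 cell were all below background in the E12.5 cell. Epas1, encoding a hypoxia-inducible transcription factor, was at least 100.1-fold higher (signal 23691 in the P0 cell), the fibronectin gene Fn1 at least 94.97-fold (22481) and the LIM protein gene Crip1 at least 91.7-fold (21716). The glycolytic aldolase gene Aldoc was at least 76.0-fold, the PDZ and LIM domain gene Pdlim3 at least 75.8-fold and S100a10, which encodes an annexin partner, at least 75.3-fold higher. The potassium channel subunit gene Kcnmb4 followed at 70.5-fold, Rlbp1 at 68.1-fold, the amino acid transporter gene Slc38a5 at 63.2-fold, the mitochondrial iron-sulfur protein gene Cisd1 at 62.6-fold, the tensin gene Tns3 at 61.8-fold and Dlc1 at 61.3-fold, each as a lower bound. Epas1, Fn1, Aldoc, S100a10, Cisd1, Tns3 and Dlc1 each had 1 further probe set above the limit, and each of these was also at least 4-fold higher in the P0 cell.

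The 12 named genes with the largest excess in the E12.5 cell were likewise all below background in the P0 cell. The imprinted zinc finger gene Plagl1 was at least 66.5-fold higher (signal 22282 in the E12.5 cell), the phosphoinositide phosphatase gene Mtm1 at least 57.7-fold (19331), the nuclear receptor gene Nr2f1 at least 49.0-fold (16401) and the transcription cofactor gene Dach1 at least 44.5-fold (14914). Shisa2 was at least 41.8-fold higher, the ubiquitin ligase gene Rnf139 at least 41.0-fold, Fam98a at least 40.0-fold and Mcm2, a subunit of the replicative helicase, at least 39.7-fold. Coro7 (39.5-fold), the intraflagellar transport gene Ift74 (39.1-fold), the histone methyltransferase gene Ezh2 (39.1-fold) and Ddt (38.4-fold) completed the 12, again as lower bounds. Coro7 had 3 further probe sets above the limit, all at least 4-fold higher in the E12.5 cell. The second probe sets of Plagl1 and Dach1 had the same sign but differed by less than 4-fold. The ratio of Dach1 depended on the settings, with a log2 value of -1.62 under quantile normalisation and -1.55 with the mean over probe sets. With the mean over probe sets Mtm1 (-1.13), Plagl1 (-1.92), Rnf139 (-1.97) and, on the P0 side, Dlc1 (0.53) also lost their 4-fold difference, as Plagl1 (-1.84) did without cross-hybridising probe sets. With the casein kinases kept among the background genes, 10 of these 12 genes did, all but Plagl1 and Mtm1.

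Most of the listed DNA replication genes were at least 4-fold higher in the E12.5 cell. Of 18 S-phase genes, 15 were above background in the E12.5 cell and 4 in the P0 cell, and 10 were at least 4-fold higher in the E12.5 cell and 0 in the P0 cell. Besides Mcm2, the helicase genes Mcm6 (at least 37.5-fold), Mcm5 (at least 17.4-fold), Mcm4 (at least 16.1-fold) and Mcm3 (4.05-fold), the DNA ligase gene Lig1 (at least 17.4-fold) and cyclin E1 (Ccne1, at least 10.3-fold) belonged to these. The P0 signal of Mcm6, 315, lay just under the limit. Pcna (10650 in the E12.5 cell and 6034 in the P0 cell), Mcm7 (13201 and 4942) and Rrm1 (2116 and 1720) were above background in both and differed by less than 4-fold. The median log2 ratio of the list was -3.06, at percentile 0.01 of the matched random lists, which became 3.43 with the casein kinases kept among the background genes. Of 20 genes of G2 and mitosis, Cenpa (280) was the only one above background in the E12.5 cell, and Bub1b (781) and Hmgb2 (932) in the P0 cell. With the limit at the 95th percentile or from bacterial controls, 3 were above it in the E12.5 cell and 8 in the P0 cell, the opposite direction to the S-phase genes. Of 11 cell cycle inhibitor genes, 6 were above background in the E12.5 cell and 4 in the P0 cell, with a median log2 ratio of -2.22 at percentile 0.03, which became 9.86 with the mean over probe sets. Cdkn1c (8.58-fold), Btg2 (at least 8.33-fold), Cdkn1b (4.85-fold) and Cdkn2d (at least 4.67-fold) were higher in the E12.5 cell, and Cdkn2c (at least 8.15-fold) in the P0 cell.

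Several retinoic acid pathway genes were also higher in the E12.5 cell. Of 19 genes, 10 were above background there against 1 in the P0 cell, and 7 were at least 4-fold higher in the E12.5 cell and 0 in the P0 cell. They were the retinaldehyde dehydrogenase genes Aldh1a1 (at least 35.7-fold) and Aldh1a3 (at least 17.6-fold), which make retinoic acid, the retinoic acid-binding protein genes Crabp1 (at least 23.8-fold) and Crabp2 (at least 4.57-fold), the vitamin A uptake receptor gene Stra6 (at least 11.9-fold) and the receptor genes Rxrb (at least 7.40-fold) and Rxra (at least 4.29-fold). The P0 signal of Aldh1a3, 300.1, lay just under the limit. Rdh10 was the member above background in both, with the higher signal in the P0 cell (2831 against 1688). The list's median log2 ratio was -2.54, at percentile 0.19.

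**Figure D3:**
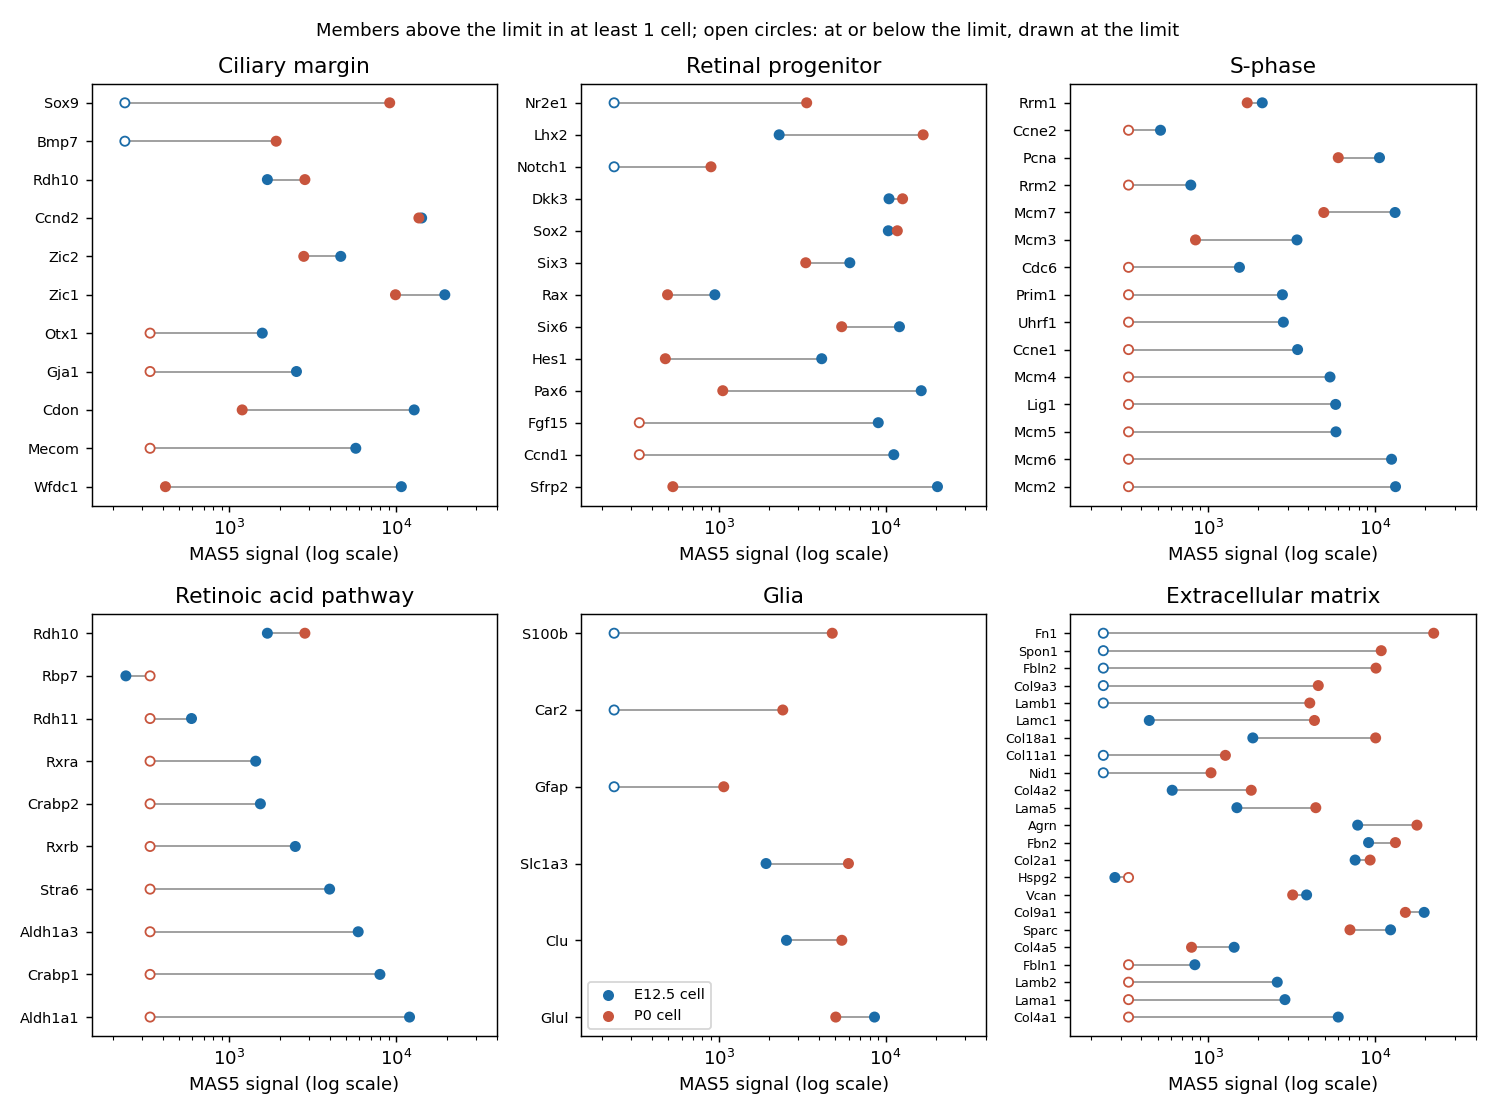
MAS5 signal (x axis, log scale) in the E12.5 cell (blue) and the P0 cell (red) of the members of 6 lists that were above the limit in at least 1 cell; open circles were at or below the limit of 237 or 335 and are drawn at it. In the S-phase panel 11 of 15 P0 circles and in the retinoic acid panel 9 of 10 are open, while the glial panel has 3 open E12.5 circles and no open P0 circle.

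More glial and extracellular matrix genes were at least 4-fold higher in the P0 cell than in the E12.5 cell (3 against 0 and 9 against 3), but most members of both lists were not. Of 11 glial genes, 6 were above background in the P0 cell and 3 in the E12.5 cell. The calcium-binding protein gene S100b (at least 20.2-fold), the carbonic anhydrase gene Car2 (at least 10.2-fold) and the intermediate filament gene Gfap (at least 4.53-fold) were above background in the P0 cell only. The glutamate transporter gene Slc1a3 (1922 in the E12.5 cell and 5984 in the P0 cell), Clu (2547 and 5461) and the glutamine synthetase gene Glul (8569 and 5024) were above it in both and differed by less than 4-fold. The median log2 ratio was 1.91, at percentile 97.7, which became 92.2 with the mean over probe sets, 92.5 without cross-hybridising probe sets and 93.3 without matching. Of 31 matrix genes, 18 were above background in the P0 cell, 16 in the E12.5 cell and 11 in both. Besides Fn1, those higher in the P0 cell included Spon1 (at least 46.1-fold), the fibulin gene Fbln2 (at least 42.9-fold), Col9a3 (at least 19.3-fold) and the laminin genes Lamb1 (at least 17.2-fold) and Lamc1 (9.74-fold). Those higher in the E12.5 cell were Col4a1 (signal 6032 in the E12.5 cell and 15.5 in the P0 cell), Lama1 (at least 8.63-fold) and Lamb2 (at least 7.77-fold). A second probe set of Col4a1 had the same sign but did not reach 4-fold. The matrix list had a median log2 ratio of 1.18, at percentile 99.7. The median became 0.39 with the arrays scaled to the spike-ins, and the percentile 90.9 with the mean over probe sets.

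Several genes of the FGF and MAP kinase pathway differed in both directions. Of 16 genes, 5 were at least 4-fold higher in the P0 cell, all of them below background in the E12.5 cell. They were the ETS transcription factor genes Etv5 (at least 45.1-fold) and Etv4 (at least 16.9-fold) and the feedback inhibitor genes Spry1 (at least 40.2-fold), Dusp6 (at least 18.2-fold) and Spred1 (at least 5.92-fold). Fgf15 and the receptor gene Fgfr2 (at least 6.01-fold) were higher in the E12.5 cell. A second probe set of Fgfr2 had the same sign but did not reach 4-fold. The list's median log2 ratio was 1.66, at percentile 96.5. It was 0.25 at percentile 60.2 with the limit at the 95th percentile and 0.76 at percentile 66.2 with the limit from bacterial controls.

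Other signalling lists were divided between the cells. Of 27 Wnt pathway genes, 10 were above background in each cell, and 4 were at least 4-fold higher in each direction. Nkd1 (at least 10.7-fold), the co-receptor gene Lrp6 (at least 6.39-fold), Znrf3 (5.61-fold) and Fzd3 (4.79-fold) were higher in the P0 cell, and Sfrp2, Fzd2 (at least 17.5-fold), Fzd1 (at least 11.3-fold) and Tcf7l1 (4.27-fold) in the E12.5 cell. A second probe set of Fzd2 above the limit did not share this sign. Of 26 BMP and TGF-beta genes, 9 were above background in the E12.5 cell and 8 in the P0 cell. Id1 (at least 20.1-fold) and Bmp7 were higher in the P0 cell, and Smad1 (at least 4.21-fold) and Bmpr1b (at least 4.10-fold) in the E12.5 cell, while Id3 had signals of 18550 in the E12.5 cell and 4818 in the P0 cell. Of 18 Notch genes, 6 were above background in the E12.5 cell and 5 in the P0 cell, with Notch3 at least 13.0-fold higher in the P0 cell and Jag1 at least 5.84-fold higher in the E12.5 cell. Further probe sets of Notch3, Jag1, Smad1 and Tcf7l1 above the limit had the same sign but did not reach 4-fold. Of 12 hedgehog genes, 6 and 5 were above background, and the receptor gene Ptch1 was 9.95-fold higher in the P0 cell. The median log2 ratios of the Wnt, BMP, Notch and hedgehog lists were -0.08, 0.83, -0.80 and -0.71, at percentiles 40.9, 90.8, 16.5 and 22.8. The mean of the hedgehog list, 0.10, had the opposite sign to its median. The Wnt median was 0.28 with quantile normalisation, and the Wnt and BMP medians were -0.95 and -1.40 with the mean over probe sets.

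Most housekeeping, ribosomal protein, oxidative phosphorylation and proteasome genes were above background in both cells. All 13 housekeeping genes exceeded the limit in the E12.5 cell and 11 in the P0 cell, where Hprt and Tbp fell below it. Gapdh had signals of 38226 in the E12.5 cell and 27028 in the P0 cell, and Eef1a1 had 41332 and 28972. Of 49 ribosomal protein genes, 42 were above background in each cell, with a median log2 ratio of -0.61 at percentile 0.615, which became -0.13 with quantile normalisation at percentile 9.11. Of 95 oxidative phosphorylation genes, 81 and 74 were above the limit in the E12.5 and P0 cells, with a median log2 ratio of -0.39. Of 39 proteasome genes, 34 and 29 were, with a median of -0.55, 8 being at least 4-fold higher in the E12.5 cell (Psmd13, at least 30.3-fold, and Psma1, 13.3-fold, among them). The immunoproteasome gene Psmb10 was 33.2-fold higher in the P0 cell. For 17 glycolytic genes the counts were 13 and 14, with a median of -0.26 and a mean of 0.21. For 26 histone and chromatin protein genes they were 12 and 9, with a median of -0.83, and for 12 apoptosis genes 6 and 7, with a median of -0.61 and a mean of 0.29. The apoptosis median was 0.31 without cross-hybridising probe sets. For 13 stem cell genes they were 7 and 6, with a median of -0.09 (0.11 with the mean over probe sets), and for 25 immediate early and stress genes 12 and 10, with a median of 0.34, which became -0.45 when the arrays were scaled to the spike-ins. The immediate early gene Fos had signals of 5535 in the E12.5 cell and 6292 in the P0 cell, and Ier3 was at least 56.9-fold higher in the P0 cell.

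A total of 22 lists had at least 5 members above the limit in at least 1 cell. Of these, 4 lay in the lowest 2.5% of the matched random lists and 3 in the highest 2.5%. For lists of independently drawn genes, 0.55 would be found on each side. The lists on the E12.5 side were S-phase, cell cycle inhibitor, retinoic acid pathway and ribosomal protein genes. The lists on the P0 side were ciliary body and iris, extracellular matrix and glial genes. Both sides depended on the settings. On the P0 side 1 list remained in the highest 2.5% with the mean over probe sets, 1 without cross-hybridising probe sets and 0 without matching. With the limit at the 95th percentile the ciliary body (96.8) and matrix (97.0) lists left it. The ciliary body list also left it with bacterial controls (97.4). On the E12.5 side 1 list, ribosomal protein genes, remained in the lowest 2.5% with the casein kinases kept among the background genes. Ribosomal protein genes left it with quantile normalisation (9.11) and without matching (4.45), and cell cycle inhibitor genes with the mean over probe sets (9.86) and the pseudocount (2.80). Retinal progenitor genes entered it with the limit at the 95th percentile (1.95), bacterial controls (1.84), quantile normalisation (1.53) and the mean over probe sets (1.70). The percentiles describe these 2 arrays, and genes within a list are not independent replicates. Lists also share genes, so they are not independent of each other. Col18a1, Col9a1 and Fbn2 belong to both the ciliary body and the matrix list.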

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

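Control probe sets for 18S ribosomal RNA, which the comparisons do not use, gave signals in the E12.5 cell of 7813 for the 3' part, 10356 for the middle and 10783 for the 5' part, all above the limit of 237. In the P0 cell these signals were 258, 378 and 1696 against a limit of 335, so that the E12.5 signal was at least 23.3 times as high for the 3' part, 27.4 times for the middle and 6.36 times for the 5' part. The 18 hybridisation spike-in probe sets were brighter on the P0 array, by a median of 1.83-fold, with an SD of the log2 ratio between them of 0.17. The ratio of the 3' to the 5' control probe set of beta-actin was 6.17 in the E12.5 cell and 2.20 in the P0 cell, and that of Gapdh was 1.06 and 1.43.

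Among the 10092 probe sets with several or no gene symbols, other than control probe sets, 1052 were above the limit in the E12.5 cell, 909 in the P0 cell and 563 in both. They are not named here.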

How the results depend on the processing

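No paired analysis was possible because there was 1 cell per age, and for the same reason no replicate could be left out. The alternatives that kept casein kinases among the background genes and that scaled the arrays to the spike-ins were chosen after seeing the data. Over the counts of genes, the list counts and the list medians, 587 alternative values stayed within 1.5 times the main count or within the probe set SD of the main log2 value, 142 did not, and no list outside the central percentiles changed the sign of its median. Some of the 587 could hardly change. Scaling to the spike-ins moves signals and limits together, so counts above background stay as they were, and centring shifts every log2 ratio by only 0.02. The SD is that of single probe sets and is wide for a list median. With the spike-ins, the BMP median went from 0.83 to 0.04 and the ciliary body median from 0.95 to 0.16, both within it. Of the values of the 24 genes with the largest ratios, 116 stayed within that SD and 124 moved, none with a change of sign. Where a limit was lowered or raised, the counts follow from it by construction; for the others the cause was not tested. With the limit at the 95th percentile, 7814 genes were above background in the P0 cell, and the S-phase, retinoic acid and FGF medians were -4.26, -4.15 and 0.25. The list counts that moved were 5 glial, 4 pigment cell, 3 G2 and mitosis, 2 each of vascular, ganglion cell, lens, mesenchymal, neurogenic and surface ectoderm and 1 each of microglial and photoreceptor genes in the E12.5 cell. In the P0 cell they were 14 histone and chromatin, 10 Notch, 8 G2 and mitosis, 7 S-phase, 6 neurogenic, 5 each of amacrine and horizontal, ganglion cell and lens, 4 each of vascular and mesenchymal, 3 each of photoreceptor and pigment cell and 2 each of microglial, retinoic acid and surface ectoderm genes. With bacterial controls as the limit those medians were -4.21, -4.10 and 0.76. The list counts that moved were 5 glial, 4 pigment cell, 3 G2 and mitosis, 2 each of vascular, lens, neurogenic and surface ectoderm and 1 each of mesenchymal and microglial genes in the E12.5 cell. In the P0 cell they were 14 histone and chromatin, 9 Notch, 8 G2 and mitosis, 7 S-phase, 5 each of ganglion cell, lens and neurogenic, 4 each of vascular and mesenchymal and 2 each of microglial, photoreceptor, pigment cell, retinoic acid and surface ectoderm genes. With the pseudocount the S-phase and retinoic acid medians were -4.01 and -3.80. The mean over probe sets gave 3236 genes above background in the P0 cell, 1981 in both, 891 higher in the P0 cell and 715 in the E12.5 cell, BMP and Wnt medians of -1.40 and -0.95, and 1 list in the highest 2.5%. The list counts that moved were 6 Wnt, 4 each of BMP, ciliary body and stem cell, 2 apoptosis and 0 G2 and mitosis genes in the E12.5 cell. In the P0 cell they were 5 histone and chromatin, 4 apoptosis, 3 each of BMP, Notch, hedgehog and Wnt, 2 S-phase, 1 each of G2 and mitosis and mesenchymal and 0 each of vascular and ganglion cell genes. Without cross-hybridising probe sets, 1 list lay in the highest 2.5%, the apoptosis median was 0.31, and 0 and 1 neurogenic genes were above background in the E12.5 and the P0 cell. Without matching, 0 lists lay in the highest 2.5%. A 2-fold threshold called 2305 genes higher in the E12.5 cell, an 8-fold threshold 1026 in the P0 and 619 in the E12.5 cell, and no filter 3924 and 4115. Scaling to the spike-ins called 2057 genes higher in the E12.5 cell. Keeping the casein kinases raised the limits to 3068 in the E12.5 cell and 4509 in the P0 cell. There 1957 genes were above background in the E12.5 cell, 1291 in the P0 cell and 790 in both, 26 were higher in the P0 cell and 7 in the E12.5 cell (78.8% of calls on the P0 side), the S-phase median was -0.37, and 1 list lay in the lowest 2.5%. The list counts that moved were 9 S-phase, 7 matrix, 6 histone and chromatin, 5 each of ciliary body, immediate early and Wnt, 4 retinoic acid, 3 cell cycle inhibitor, 2 each of BMP, Notch and hedgehog, 1 each of amacrine and horizontal, apoptosis, FGF, glial, pigment cell and stem cell and 0 each of G2 and mitosis, ganglion cell, lens and neurogenic genes in the E12.5 cell. In the P0 cell they were 19 proteasome, 10 matrix, 4 retinal progenitor, 3 each of BMP and ciliary margin, 2 each of S-phase, FGF, histone and chromatin and Wnt, 1 each of amacrine and horizontal, cell cycle inhibitor, Notch, stem cell and hedgehog and 0 each of G2 and mitosis, apoptosis, vascular, ganglion cell, mesenchymal, neurogenic and retinoic acid genes. Over all alternatives that gave one, the percentile of the S-phase list ran from 0 to 3.43, of the retinoic acid list from 0 to 0.19, of the matrix list from 90.9 to 99.9, of the glial list from 92.2 to 98.9, of the ciliary body list from 84.9 to 99.9 and of the FGF list from 60.2 to 97.6. Signals near the limit, such as those of Mcm6 and Aldh1a3 in the P0 cell, cannot be told from background with confidence.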

Other observations

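The lists and tests of this part were all written after values had been seen, the tests of loss were written again to allow for the choice of lists and for the alternatives, how an alternative with too few genes counts was settled after its result, and list membership was partly prompted by genes already noticed. Some transcription factor genes that pattern the eye differed between the cells. Of 17 such genes, 6 were above background in the E12.5 cell, 4 in the P0 cell and 1, Tbx2 (1839 and 6122), in both. Besides Nr2f1 and Dach1, the E12.5 cell had the homeobox genes Meis1 (at least 23.2-fold higher), Meis2 (at least 13.8-fold) and Vax2 (at least 17.4-fold), a factor of ventral retina. The P0 cell had Vax1 (at least 20.9-fold), a factor of optic stalk, Tbx3 (at least 20.8-fold) and Eya2 (at least 3.93-fold). Of 19 Polycomb and DNA methylation genes, 15 were above background in the E12.5 cell and 11 in the P0 cell. Besides Ezh2, its partner Eed (at least 10.8-fold), Rbbp4 (10.1-fold), Cbx2 (at least 11.52-fold) and Dnmt3b (at least 7.52-fold) were higher in the E12.5 cell, and Suz12 (at least 12.04-fold) in the P0 cell. Of 18 imprinted genes, 11 were above background in the E12.5 cell, 14 in the P0 cell and 10 in both, with Ndn (26112 and 23200), Igf2 (12635 and 16332) and Grb10 (20975 and 10686) in both, Plagl1 in the E12.5 cell only and Sgce at least 14.8-fold higher in the P0 cell.

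Of 17 hypoxia response genes, 7 were above background in the P0 cell and 4 in the E12.5 cell. Besides Epas1 and Aldoc, Adm, which encodes adrenomedullin (at least 47.8-fold), and Pdk1 (at least 9.92-fold) were higher in the P0 cell, while Hif1a and the oxygen sensor gene Egln1 were at least 5.22-fold and at least 5.51-fold higher in the E12.5 cell. Of 14 MHC class I and interferon genes, 4 were above background in each cell, with B2m (15.0-fold), Psmb10 and Irf7 (at least 5.65-fold) higher in the P0 cell. Of 27 ephrin, semaphorin and Slit genes, 8 were above background in each cell, near the shares of all genes (30.8% and 28.5%). Sema6d (at least 50.4-fold), Sema5a (at least 27.0-fold) and Epha4 (at least 9.96-fold) were higher in the P0 cell, and Efna5 (26.3-fold) and Sema6a (at least 20.2-fold) in the E12.5 cell. Of 19 general neuronal genes, 5 were above background in the E12.5 cell and 0 in the P0 cell. They were Tubb3 (at least 11.3-fold higher), Vamp2 (at least 7.29-fold), Gap43 (at least 4.35-fold), Syt1 (at least 3.58-fold) and Celf4 (at least 1.48-fold). Xist, the X-inactivation RNA, had a signal of 13314 in the P0 cell and 60.6 in the E12.5 cell. The Y-linked gene Kdm5d was above background in the E12.5 cell only (685 against 1.29), and Eif2s3y, Uty and Usp9y were in neither. The cells may thus differ in sex, which was not tested and could not be told apart from age.

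The lower signal of S-phase genes in the P0 cell was set against random loss of transcripts there, but the P0 cell kept 4 of 15, where random sets of the same E12.5 signal kept a median of 11. Because this list was picked for its low value, all lists were drawn at random 10000 times, and in 0% of draws did any list, in either direction, lie as low. In 5 alternatives that share was 0.62% or less (0.45%, 0.62%, 0.12%, 0% and 0.53%), but with the casein kinases kept among the background genes, which raises the limits, 2 of 9 were kept and it was 62.7%. Because the outcome depends on the limit, random loss cannot be told apart from a difference in expression. Age, sex, cell cycle phase and differences from cell to cell stay open and were not tested.

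For the retinoic acid genes, the P0 cell kept 1 of the 10 genes above background in the E12.5 cell, where random sets of the same signal kept a median of 6. In 1.4% of draws did any list lie as low, and 1.44% was the highest share in 5 alternatives. Under these settings fewer genes were kept than loss striking all genes of the same E12.5 signal alike would leave. The draws cannot address loss that differs from transcript to transcript, so random loss is not excluded. With the casein kinases kept, where the S-phase result did not hold, fewer than 5 members were left and no test was run. Whether the result would hold there is not known. RNA quality and amplification were not tested for any pattern and stay open. In the E12.5 cell the 3' part of 18S was at least 23.3 times, the middle 27.4 times and the 5' part 6.36 times as high. The 3' to 5' ratio of beta-actin was 6.17 there and 2.20 in the P0 cell. That of Gapdh went the other way, with 1.06 and 1.43. Age, sex, position around the rim and differences from cell to cell stay open and were not tested.

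The third pattern joined the glial, matrix and FGF pathway lists, a choice made after values had been seen. The FGF list differed in both directions and lay at percentile 96.5, or 60.2 with the limit at the 95th percentile. The ciliary body list, at percentile 98.7, was not included. The E12.5 cell kept 6 of its 8 genes above background in the P0 cell, where random sets kept a median of 7. The joined lists covered 30 genes above background in the P0 cell. Of these the E12.5 cell kept 15, where random sets kept a median of 22. In 19.96% of draws the 3 lowest lists together lay as low, so random loss in the E12.5 cell cannot be told apart from a difference in expression. RNA of a mesenchymal cell cannot be told apart from expression by the cell itself either. In the P0 cell 28.5% of all genes were above background, and so were 25% of 12 abundant mesenchymal transcripts. They were Col1a2, Pdgfra and Col5a2, while Col1a1 (11.48), Col3a1 (119.9), Dcn (47.2) and Lum (7.50) were below background. Col1a2 and Pdgfra also belong to the fixed mesenchymal list, so they are not further evidence. Col5a2 was not higher in the P0 cell, with 4082 there and 4411 in the E12.5 cell. Age, sex and cell-to-cell differences stay open and were not tested.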
